A study of Arabidopsis thaliana with 6 samples.

How the data were processed

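Total RNA of 6 seedling samples was biotin-labelled and hybridised to Affymetrix arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of intensity values, positive and on a linear scale, for 22810 probe sets. The submitters' processing notes name MAS5 and RMA, without a role or version. Which of them made the table, and any scaling target, is not given in the sources used here. How the values were summarised decides how dim probe sets spread, so small values are read with care. The design text speaks of biologically independent pools for the 2 replicates. An ecotype label is absent for the mock replicate 1 sample.

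The 64 control probe sets were left out of the tests, which leaves 22746. Platform annotation lists 13513 of these for 1 gene, 503 for several and 8730 not at all, and 13436 of the 13513 were matched to RefSeq (TAIR10.1) to update symbols. A probe set that is not listed stays unnamed here. Only 57 of the 366 genes in the 18 fixed lists can be named, and 4 lists have 5 or more measured genes, the smallest number tested. SOC1, FT, LFY, AP1, FLC and SVP have no listed probe set and were not analysed here. Coordinates are not printed, because no build is named for the files.

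Values were taken to log2(value + 16) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) over all 6 arrays in 3 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount of 16 exceeds the array medians near 7, so the log2 differences understate changes in dim genes. The number of arrays, 2 per group with 3 residual degrees of freedom, limits the precision, and an exact two-sided permutation test of 2 against 2 arrays cannot go below 0.333. Gene lists were tested with camera at a preset correlation of 0.01. It called 0 lists with either the preset or an estimated correlation. A fold criterion, fixed with the rest, asked for a 2-fold difference of group means in both comparisons with both estradiol HY213 arrays beyond the other 4.

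Deviations from the group means correlated between arrays with the same replicate number, with r across probe sets of 0.693 for mock and estradiol HY213, 0.665 for mock HY213 and wild type, and 0.822 for estradiol HY213 and wild type. The first principal component, with 70% of the variance, separated the replicate numbers. With the design text's 2 rounds of the experiment, this was taken before any calls were compared as a reason to treat the number as a batch, and values with it as a block, which leaves 2 residual degrees of freedom, stand beside results they change.

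The named genes were chosen by a rule fixed before the data were examined: AGL24 and 6 flowering genes, of which only AGL24 is listed; the largest changes past the threshold in each comparison and in both; up to 4 members of each described list by smallest unadjusted p; and, where fewer than 5 pass, the probe sets of the fold criterion, as values. Genes outside it are marked where they appear. The tests were run on simulated data drawn with the real spread, with 50 probe sets at each fold over 22746. For estradiol against mock, 78% of the 2-fold, 96% of the 4-fold and 100% of the 8-fold changes were called. For estradiol HY213 against wild type these were 80%, 96% and 100%. These folds hold on the fitted log2 scale with its pseudocount, where estimates averaged 1.01 times the 2-fold change set for estradiol against mock. In dim probe sets a given fold on that scale is a larger fold in intensity, so the percentages overstate the power for intensity changes there. The alternatives tried were quantile and median normalization, pseudocounts of 1 and 64, leaving out the dimmest 25% of probe sets, other variance priors, only the 4 arrays compared, the replicate block, each array left out, an adjusted p of 0.1, a 1.5-fold criterion, and for lists an estimated correlation and fry. Runs without a pseudocount, fold counts on the deposited values, values set to the Bacillus controls, an estimated correlation with 1 array left out and 17 gene families by symbol were added after the data were seen.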

Results

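Gene expression was measured in 9-day-old Arabidopsis thaliana seedlings on 6 Affymetrix arrays, in 3 groups of 2. Line HY213 was sampled after 8 h of mock treatment and after 8 h of estradiol, and wild-type seedlings after 8 h of estradiol. HY213 is taken here to be the line that carries AGL24 under the estradiol-inducible XVE system, because it is the line named beside the wild type in the sample titles. In that system estradiol activates a chimeric transcription factor, which then switches on the transgene. AGL24 encodes a MADS-box transcription factor that promotes flowering. The deposited array medians lay between 6.95 and 7.27 intensity units. On each array, 58.2% to 72.7% of the 22746 probe sets read above the highest of the Bacillus control probe sets, which stood at 5.14 to 6.22. Arrays with the same replicate number correlated more closely across probe sets (r 0.986 to 0.993) than arrays of the same group (r 0.961 to 0.980). Probe sets are not independent replicates.

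AGL24 (AT4G24540) read 106 and 401 in estradiol-treated HY213, replicates 1 and 2, with a mean of 254 ± 209 (SD, n = 2). It read 4.98 and 4.87 in mock-treated HY213, a mean of 4.92 ± 0.077 (SD, n = 2), and 5.05 and 4.60 in estradiol-treated wild type, a mean of 4.82 ± 0.318 (SD, n = 2). Both baselines lay below the highest Bacillus control of their array. With each baseline array set at its highest Bacillus control, the induced level was at least 17.2-fold higher than mock in replicate 1 and at least 78.1-fold in replicate 2, and at least 17.1-fold and 76.1-fold higher than wild type. Ranked within each array, AGL24 stood at percentiles 92.1 and 98.0 in estradiol-treated HY213 and at 13.4 to 20.3 on the other 4 arrays. On the log2(value + 16) scale the difference was 3.43 ± 0.51 (SE) from mock and 3.44 ± 0.51 (SE) from wild type, and neither passed the adjusted p threshold of 0.05 in limma (unadjusted p 0.000386 and 0.000382, adjusted p 1 for both). With replicate number as a block the unadjusted p were 1.48e-05 and 1.46e-05 and the adjusted p 0.337 and 0.332. Without a pseudocount, a setting chosen after the data were seen, the blocked adjusted p were 0.0264 and 0.0252, against baselines not above background, and with these baselines at the highest Bacillus control they were 0.0620 and 0.0644. Without the replicate 1 array of estradiol-treated HY213, AGL24 passed with adjusted p of 0.00263 and 0.00261, and without the replicate 2 array with 0.0130 and 0.0128.

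**Figure D1:**
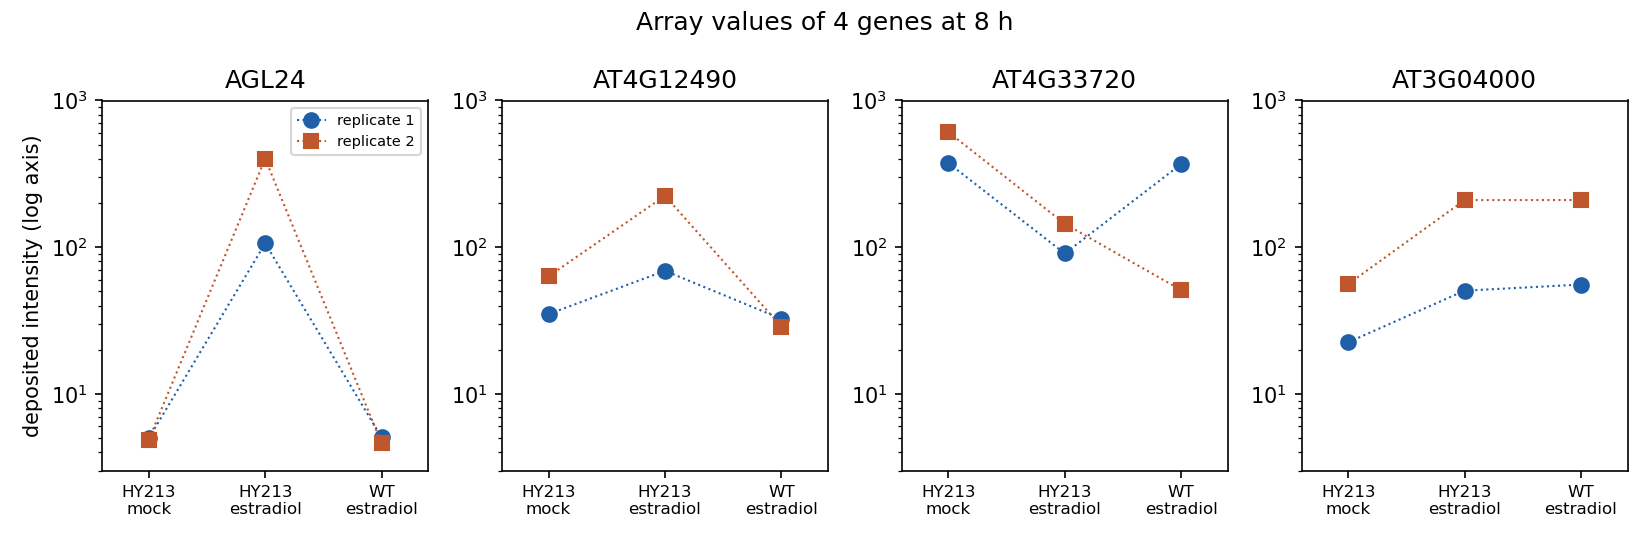
Deposited intensity on a log axis for AGL24, AT4G12490, AT4G33720 and AT3G04000 in mock HY213, estradiol HY213 and estradiol wild type. Each point is 1 array, with circles for replicate 1, squares for replicate 2 and dotted lines joining arrays of the same number. AGL24 stands at 106 and 401 in estradiol-treated HY213 and near 5 elsewhere, while AT3G04000 is higher in both estradiol groups.

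The first comparison, estradiol against mock within HY213, asks which transcripts respond when AGL24 is induced, together with any response to estradiol itself. Besides AGL24, the fold criterion names AT4G12490, which encodes a lipid transfer protein-like protein. It read 69.0 and 224 after estradiol against 34.99 and 63.3 in mock, a log2 difference of 1.17 ± 0.49 (SE). AT4G33720, which encodes a PR-1-like secreted protein, read 90.5 and 144 after estradiol against 374 and 609 in mock, a log2 difference of -1.92. AT5G35735 read 49.4 and 123 against 19.4 and 28.8, with a smaller blocked unadjusted p than AT4G12490 (0.000433 against 0.00554), and 33.4 and 109 in estradiol-treated wild type. These 2 genes were picked after their values were seen. Of the dehydrins, LTI30 read 107 and 242 after estradiol against 72.5 and 91.1, and COR47 read 751 and 602 against 533 and 511. limma called 0 of 22746 probe sets at an adjusted p of 0.05, with 272 at an unadjusted p under 0.05 where chance gives 1137. The blocked model also called 0, with 962 at an unadjusted p under 0.05. The unblocked model counts the difference between the replicate numbers as spread, here and in the other comparisons. Its counts below chance therefore do not show that transcripts were unchanged. On the log2(value + 16) scale, 3 probe sets were 2-fold higher within both replicates and 1 was 2-fold lower. AGL24 and 2 probe sets not listed for a gene were higher, and AT4G33720 was lower. On the deposited values 9 were higher, among them AT5G35735 and AT3G04000, and 2 were lower, AT4G33720 and AT5G06630. A fit without the replicate 1 array of estradiol-treated HY213 leaves a lone array in that group. Besides AGL24, what passed there was mostly probe sets high on the replicate 2 array alone, described below. Their log2 differences from mock went up to 2.82. Without the replicate 2 array, AGL24 differed by 2.55.

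The gene lists fixed beforehand held few named probe sets on this array, and 0 members passed over all probe sets in any list. Of the flowering-time list, 9 genes were measured, 3 higher and 6 lower after estradiol. They included the bZIP gene FD (4.60 and 4.46 after estradiol, 5.35 and 4.71 in mock) and the MADS-box gene AGL19 (4.57 and 4.66 against 4.1 and 4.54). All of these FD and AGL19 values lay under the highest Bacillus control of their array, so their directions carry no weight. SMZ read 8.68 and 9.45 against 8.07 and 8.03. In the auxin list, 4 of 7 genes were higher, among them GH3.3, an auxin-conjugating enzyme gene, at 24.3 and 225 against 21.9 and 50.2. LBD29 read 4.87 and 4.14 against 5.51 and 4.62, also under these controls. The heat-shock list had 5 measured genes with a median log2 difference of 0.022 and a camera adjusted p of 0.315, and the photosynthesis list 5 genes with a median of -0.11 and an adjusted p of 0.359. Adjusted over the list alone, the thionin gene THI2.1 (7.09 and 5.93 after estradiol, 5.21 and 5.15 in mock) passed, 1 of 2 measured jasmonate genes, as did RR16 (4.62 and 5.31 against 6.82 and 6.20), 1 of 2 cytokinin genes. Both lie near background. In the blocked model the dehydrins LTI30 and COR47 also passed over their list alone, 2 of 4 measured cold and drought genes.

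The second comparison, estradiol-treated HY213 against estradiol-treated wild type, holds the chemical constant, so that the line differs. AT4G12490 read 69.0 and 224 in HY213 against 32.4 and 28.8 in wild type, a log2 difference of 1.62 ± 0.49 (SE). AT3G16530, which encodes a lectin-like protein and was picked after its values were seen, read 117 and 203 against 82.8 and 105, a log2 difference of 0.64 ± 0.30 (SE). Neither passed the threshold (adjusted p 1 for both). In AT4G33720 the replicates differed in direction, at 90.5 against 368 in replicate 1 and 144 against 51.0 in replicate 2. limma called 0 of 22746 probe sets, with 176 at an unadjusted p under 0.05 against 1137 by chance. The blocked model called 0, with 826 at an unadjusted p under 0.05. On the log2(value + 16) scale, AGL24 alone was 2-fold higher within both replicates, and 0 were 2-fold lower. On the deposited values 3 were higher and 0 lower: AT4G12490 was also 2.13- and 7.79-fold higher, and the plastid gene psaJ, picked after its values were seen, 3.02- and 2.03-fold. Without the replicate 1 array of estradiol-treated HY213, what passed besides AGL24 was again mostly probe sets high on the replicate 2 array alone. Their log2 differences from wild type went up to 2.75. The seed maturation gene AT2G28490 also passed, at 0.40. Without the replicate 2 array, AGL24 differed by 2.55.

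In this comparison 0 of the 4 testable lists passed in camera. The lowest adjusted p was 0.223, in the heat-shock list, where 3 of 5 genes were higher in both replicates. All 5 read within a few units of the Bacillus controls. In the photosynthesis list, 4 of 5 genes read lower in HY213 in both replicates, for example LHCB4.1, a light-harvesting protein of photosystem II, at 908 and 1123 against 1044 and 1286. The list's adjusted p was 0.283. Of the flowering genes, SNZ read 6.34 and 5.83 against 7.16 and 5.79, and GI, a clock-associated regulator, 52.4 and 69.4 against 55.8 and 76.7. THI2.1 read 7.09 and 5.93 against 5.29 and 5.30, and passed over its list alone in the blocked model.

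Differences present in both comparisons were sought, as the design text uses both to set aside responses to estradiol. With both estradiol HY213 arrays beyond the other 4 and a 2-fold difference in each comparison, 2 probe sets were higher, AGL24 and AT4G12490, and 0 were lower. At 1.5-fold there were 7 higher and 0 lower, of which 3 were listed for 1 gene, AGL24, AT4G12490 and AT3G16530. Of the unlisted ones, 2 were among the probe sets high on the estradiol HY213 replicate 2 array alone, with replicate 1 log2 differences of 0.12 and 0.026 from mock. The 2-fold count was 4 without the wild-type replicate 1 array, 8 without the wild-type replicate 2 array, 49 without estradiol HY213 replicate 1 and 24 without replicate 2. Each of these leaves the groups unbalanced over the 2 replicates, so the difference between the replicates enters the counts. Without an estradiol HY213 array, only 1 array has to lie beyond the other 4, which is a looser criterion. Both comparisons share the estradiol HY213 arrays. The log2 differences of the 2 comparisons correlated across probe sets with r 0.403, below the 0.501 of simulated unchanged groups with the replicate effect. Their covariance was 0.00504, where the simulation gave 0.00409 with the replicate effect and 0.0133 without. The simulation with it gave 0.08 probe sets on average at 2-fold, 1 at most, and 0.86 at 1.5-fold, 3 at most. Without it the simulation gave 11.3 at 2-fold, from 4 to 18, and 65.9 at 1.5-fold, from 48 to 84, above the observed counts. That setting draws the difference between the replicates as independent spread of each array, while the real arrays share it within a replicate. It is therefore no fair baseline for the observed counts. Pairing 1 comparison in 1 replicate with the other comparison in the other replicate removes the shared array and leaves single arrays. Estradiol against mock in replicate 1 with estradiol HY213 against wild type in replicate 2 gave r 0.259 and a covariance of 0.00503. The opposite pairing gave r -0.00847 and a covariance of -0.000207, so the pairings differed. The simulated data also share the estradiol HY213 arrays, so sharing is already in their covariances. The source of any excess stays open. Replicate 1 with replicate 2 of the same comparison gave r 0.0573 for estradiol against mock and 0.205 for estradiol HY213 against wild type. For wild type against mock HY213 it gave 0.0284. With no fold minimum, 1764 probe sets had both estradiol HY213 arrays beyond the other 4, which is 7.76% where exchangeable arrays give 13.3%. The simulation with the replicate effect gave 1670, from 1590 to 1740.

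**Figure D2:**
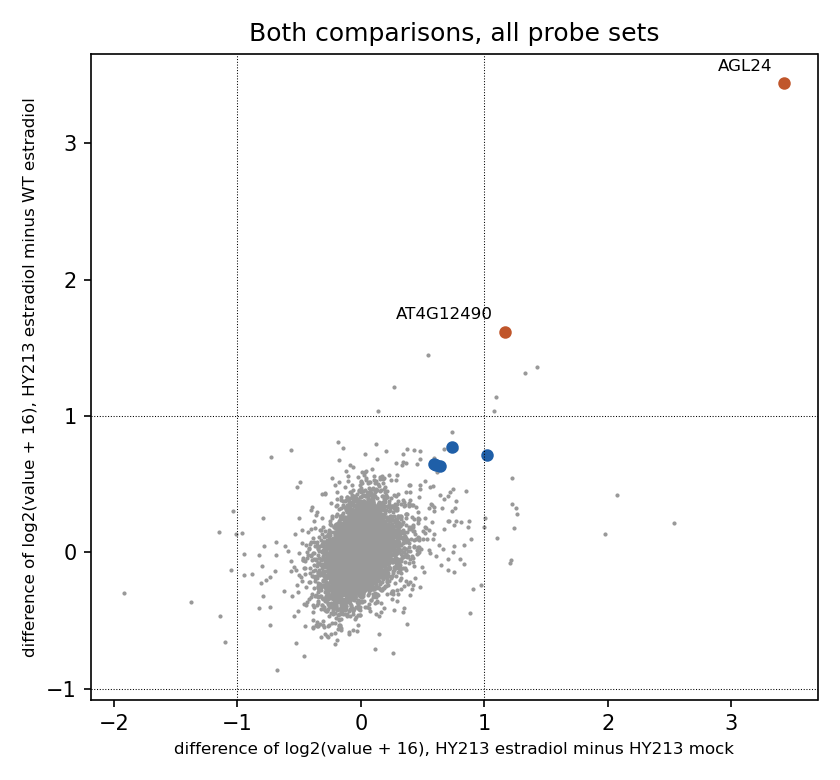
Difference of log2(value + 16) for each of the 22746 probe sets, with HY213 estradiol minus mock on the x axis and HY213 estradiol minus wild-type estradiol on the y axis, as means over 2 replicates. Orange points met the 2-fold criterion in both comparisons (AGL24 and AT4G12490) and blue points the 1.5-fold criterion only; dotted lines mark 2-fold, and AGL24 lies at 3.43 and 3.44.

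The remaining contrast, estradiol-treated wild type against mock HY213, mixes the line with the chemical. AT3G04000, a short-chain dehydrogenase gene, read 55.6 and 210 against 22.5 and 56.0, a log2 difference of 1.27, and estradiol-treated HY213 read 50.5 and 209. Other differences of the same kind were in GH3.3 (35.4 and 249 against 21.9 and 50.2), in the zinc-finger gene STZ (16.8 and 104 against 13.9 and 24.9) and in LTI30 (95.5 and 205 against 72.5 and 91.1). AT5G06630, whose probe set is of a type that can bind related transcripts, read 15.8 and 6.93 against 30.5 and 20.13, and 13.0 and 9.36 in estradiol-treated HY213. AT3G04000 and AT5G06630 were picked after their values were seen, as the higher and the lower gene with the smallest blocked p (0.000369 and 9.79e-05) among genes 1.5-fold apart on the log2(value + 16) scale. limma called 0 of 22746 probe sets, with 268 at an unadjusted p under 0.05 against 1137 by chance, and the blocked model called 0, with 1215. In camera 0 of the 4 testable lists passed. Adjusted over the list alone in the blocked model, STZ, LTI30 and COR47 passed. On the log2(value + 16) scale, 1 probe set, not listed for a gene, was 2-fold higher within both replicates, and 0 were lower. On the deposited values 5 were higher, of which AT3G04000 was named, at 2.48- and 3.74-fold, and 2 were lower, of which GSTU20, a glutathione transferase gene, was named (6.03 and 4.38 against 13.9 and 14.0). GSTU20, also picked after its values were seen, lies under 1.5-fold on the log2(value + 16) scale and had a blocked p of 1.39e-05.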

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

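The results without a pseudocount were added after the data were seen. The counts of calls stayed at 0 in 15 of 18 alternatives for each main comparison and for both together, and in 18 of 18 for wild type against mock HY213. Leaving out 1 array gave 0 to 13 calls for estradiol against mock, 0 to 16 for estradiol HY213 against wild type and 0 to 13 in both, with a lone array assumed to vary like the other groups. AGL24 then ranged from 2.55 to 4.32 against mock and from 2.55 to 4.325 against wild type, the fold criterion from 2 to 49 probe sets, and the lists past the threshold from 0 to 2. These were heat shock (adjusted p 0.000167 and 2.49e-05) without estradiol HY213 replicate 1 and photosynthesis (0.0217 and 0.0287) without replicate 2, all lost with an estimated correlation (adjusted p = 0.211, 0.176, 0.586 and 0.577). Leaving 1 array out drops its group's spread and lets replicate differences enter. GH3.3 for estradiol against mock ranged from -0.31 to 2.27 and STZ from -0.040 to 1.46. STZ for wild type against mock HY213 ranged from -0.095 to 1.78. All fell below 0 without 1 replicate 2 array, none within a replicate.

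The fold criterion gave 7 probe sets with a pseudocount of 1, 1 with a pseudocount of 64, 7 at 1.5-fold and 7 without a pseudocount, where less shrinkage of dim values lets more pass. Without a pseudocount and with the replicate block, 1 probe set was called in each comparison and in both, AGL24, with log2 differences of 5.39 and 5.42 from baselines not above background; with these at the highest Bacillus control the calls were lost (adjusted p 0.0620 and 0.0644). AGL24 kept its direction in all 17 alternatives of each comparison, with adjusted p from 0.00260 to 1. With the replicate block alone the counts stayed at 0, 0, 0 and 0, the lists at 0, and AGL24 at 3.43 and 3.44, so it changed no call among these; beyond them it added calls in 3 gene families and, over lists or families of over 1 gene alone, in LTI30, COR47, STZ, THI2.1 and psaJ. The family calls were lost with an estimated correlation (blocked adjusted p = 0.935, 0.830 and 0.830). AT4G12490 kept its direction in 17 of 17 alternatives in both comparisons, with adjusted p from 0.389 to 1. With 1 array left out it ranged from 0.42 to 1.92 against mock and from 0.87 to 2.37 against wild type. Under the same step AT3G16530 ranged from 0.23 to 0.95 and from 0.28 to 1.003, LTI30 for estradiol against mock from 0.34 to 1.41, and AT3G04000 for wild type against mock HY213 from 0.44 to 2.1. The robust prior was not run for the lists, since camera takes none, and SOC1 has no value under any setting. Signal over background limits the dim genes: in the fixed lists, most flowering genes and all measured heat-shock genes read within a few units of the Bacillus controls.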

Other observations

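The seed gene test and the power test were set out before their results were seen; the other tests here, and the gene families, were chosen afterwards. Of 17 gene families, 0 passed in the unblocked model. With the replicate block, 3 passed for estradiol HY213 against wild type: plastid-encoded genes higher (69 genes, adjusted p = 0.00540), and xyloglucan endotransglucosylases (10 genes) and ubiquitin-conjugating enzymes (13 genes) lower, both with adjusted p = 0.0292. With an estimated correlation the blocked adjusted p were 0.935 for the plastid genes and 0.830 for both other families. Adjusted over the family alone, psaJ passed among the plastid genes, higher in the same comparison and with the block only, and GSTU20 in its family of 11 passed with and without it, lower in both estradiol groups than in mock. Of the 10 xyloglucan endotransglucosylases, which remodel cell walls, 7 read lower in both replicates.

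Both estradiol groups stood apart from mock HY213 in the same direction in 6 probe sets at 1.5-fold in both replicates on the log2(value + 16) scale, 5 higher and 1 lower, where 0.0388 and 0.0492 are expected from independent replicates. On the deposited values there were 15, these 6 among them, 11 higher and 4 lower, where 0.660 and 0.766 are expected. These expectations treat all probe sets as equally able to reach 1.5-fold. Probe sets differ in brightness and spread, so the expectations may be too low, and the excess is not read as a response to estradiol. With values under an array's highest Bacillus control set to it, 10 of the 11 and all 4 still met it; AT3G22060, at 4.38 in mock replicate 1, did not. The other named higher ones were AT3G04000, AT5G35735, AT4G20860, AT4G13180 and JRG21, and the named lower ones GSTU20 and AT5G06630. On the deposited values AT3G04000 was 2.36 times the mock level in replicate 1 and 3.74 times in replicate 2 as a mean of both groups, AT5G35735 2.09 and 4.03 times, and AT5G06630 0.470 and 0.400 times. None passed in limma with the block (0 of 22746, smallest adjusted p 0.413 with 1145 at an unadjusted p under 0.05, and 0.344 with 1173 without a pseudocount). Within a replicate both estradiol groups are set against the same mock array, so the 2 groups are not independent evidence.

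Estradiol HY213 replicate 2 held 13 probe sets at 4 times or more the level of each of the other 5 arrays, while the other arrays held 0 (28 against 0 to 4 at 2-fold). The only named one is PAP85, a seed storage protein gene, at 42.8 against 5.01 to 9.90. Of 26 other measured seed maturation genes, 61.5% were highest on that array (16 of 26, one-sided exact binomial p = 3.44e-07, though the genes are not independent), for example AT2G28490 at 11.03 against 4.43 to 4.97, so RNA from seeds or seed coats in that pool is a candidate source, though most of these genes lie near background. A graded response to AGL24, an explanation narrowed to that form after its value was seen, is argued against by a median log2 difference of -0.093 (SD 0.186) from mock in replicate 1 over the same 13 probe sets, which a 4-fold level over the 4 mock and wild-type arrays picks without the replicate 1 estradiol HY213 array. A response that needs the higher AGL24 level of replicate 2 stays open.

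Replicate 2 differed from replicate 1 in 2510 of 22746 probe sets in the blocked model, 1471 higher and 1039 lower. Among plastid-encoded genes 34 of 69 were lower and 5 higher (camera adjusted p = 1.36e-11, and 0.630 with an estimated correlation), such as ndhD at 60.6, 67.6 and 63.2 against 565, 607 and 418. A lower share of green tissue is argued against by nuclear photosynthesis genes, with a median log2 difference of 0.39 (SD 0.338) over 5 genes. Only 1 of them was called higher, and the list's camera adjusted p was 0.0433, or 0.622 with an estimated correlation. Degradation stays open: 1 of 3 control ratios of 3-prime to 5-prime signal, that of actin, was lower in replicate 2 in all 3 groups (3.87 to 1.89, 2.01 to 1.86 and 2.80 to 2.06), and the GAPDH ratios went both ways. A lower share of organellar RNA in the labelled target may account for it: 9 of 15 mitochondrial genes were also lower and 1 was higher. The camera adjusted p of these genes was 5.16e-05, or 0.622 with an estimated correlation. Their median of -0.38 leaves this open because most lie near background. Background itself was lower in replicate 2, where the highest Bacillus control read 5.14 to 5.31 against 5.99 to 6.22 in replicate 1.

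Whether low power explains the few calls is open. In simulation 96% of changes of 4-fold on the fitted scale with its pseudocount were called, which met the bound set beforehand against low power. That bound is read as wrong, in part because the simulation gives changed probe sets the spread of unchanged ones. AGL24, at 106 and 401, differed between its induced pools far more and was missed. This reading was chosen after AGL24 was seen. The simulation also holds 50 changed probe sets at each fold in the same data set, which eases the adjusted threshold. Whether the spread or the threshold cost AGL24 its call was not tested. Its percentages therefore overstate the power where few probe sets change. They also overstate it for intensity changes in dim probe sets, where a 4-fold change on the fitted scale is a larger fold in intensity.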
